A study of Mus musculus with 15 samples.

How the data were processed

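RNA-seq libraries of 15 tissue samples from the mouse brain at embryonic day 12.5 were analysed, with 3 samples each of ventral midbrain, dorsal midbrain, alar plate, forebrain and hindbrain. The labels do not say which part of the brain the alar plate samples came from, so they may adjoin or overlap another region, such as the dorsal midbrain. Per the labels' protocols, the mice carried a green fluorescent protein driven by the promoter of tyrosine hydroxylase, the enzyme that begins dopamine synthesis, regions were dissected under a microscope, and libraries were made from 200 ng of RNA with an Illumina TruSeq kit. The labels do not say whether the samples of a region came from separate embryos, so p-values measure the spread between these samples, which may be partly technical.

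The authors deposited one table of RPKM values (reads per gene model, scaled for its length and for the mapped reads of the library) for 24264 genes, with 1 column per sample and no pooled column. The submitters' processing notes name the aligner Bowtie and the genome build mm9. The version of the aligner, the annotation, the counting and any filter are not given in the sources used here, nor whether counting used strand. Genes that share reads with near-identical copies or overlapping genes are uncertain for that reason, and 2 entries of Pde4b stand for 2 loci of that name. The reference at hand is of another build (GRCm38), so no coordinates are given, and it served only to match older gene symbols in the lists.

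Reads were recovered from the deposited RPKM values. In each library a gene's RPKM values are whole multiples of what 1 read is worth for that gene, and the step was found by comparing low values between libraries. Of the 16612 genes above 0 in at least 10 libraries, 16563 (99.7%) came out whole in every library, with a tolerance of 0.02 reads for small values and at most 0.15. The same procedure on a simulated table of 16458 such genes gave whole reads for 97.8%, and 100% of those had the true reads in all libraries. The recovered reads in gene models sum to between 8048160 and 12170238 per library. For a gene of median length, 3 reads corresponded to 0.0748 to 0.113 RPKM, and a value below that was treated as not detectable at this depth. Such a floor covers counting error only.

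Differences were tested with limma (version 3.58.1, R 4.3.3) on log2(RPKM + 1) with a variance trend, in one fit of all 5 regions, for the 13745 genes with an RPKM of at least 1 in at least 3 libraries. Each region was compared with the unweighted mean of the other 4, the ventral midbrain with each other region, and the dorsal midbrain with the alar plate. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with an adjusted p under 0.05 were called. Differences are on the log2(RPKM + 1) scale, which understates the change of weakly expressed genes. On simulated data of 13487 genes, the comparison of the ventral midbrain with the other regions recovered 80.6% of genes changed by 2-fold and 98% of those changed by 4-fold, with 2.75% of calls false. For the ventral against the dorsal midbrain the shares were 68.4% and 93%, with 3.61% of calls false. The simulated reads were drawn independently for each gene and library. Only the ventral midbrain was changed, at genes above a minimum mean of reads. The simulation held no length trend, no deviations shared by the genes of a library and no differences between the other regions. These shares therefore need not hold for the real libraries.

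Gene lists were fixed before the data were examined: midbrain dopaminergic progenitor and floor plate, midbrain dopaminergic neuron, ventral midbrain motor and red nucleus neurons, midbrain GABAergic neuron, tectum and dorsal neural tube, midbrain and isthmus, telencephalon, diencephalon and hypothalamus, Hox genes, hindbrain neurons, the PBX and MEIS family, pan-neuronal genes, neural progenitor and radial glia, proliferation, hedgehog signalling, Wnt signalling, axon guidance, laminins and basement membrane, immediate early and stress genes, sex-linked genes, and markers of erythroid cells, endothelium, meninges and mesenchyme, microglia and macrophages, choroid plexus, and cranial ganglion and muscle. Lists share some members, and those of other cell types and of some regions hold genes that the tissues studied also express. They were tested with camera at its preset correlation and again with an estimated correlation, and with fry, as 1 family of 150 tests. The rule for named genes, also set beforehand, took the 10 highest and 10 lowest differences per region (5 and 5 per pair of regions) among called genes whose 3 samples all lay on one side of the samples compared, with a mean of at least 5 RPKM on the higher side, the 10 largest smallest-of-4 differences with at least 5 RPKM for genes higher in the ventral midbrain than in each other region, up to 4 called members of each list and others a sentence on the list needs, and Th, Pitx3, Nr4a2, Lmx1a, Foxa2, En1, Otx2, Pax7, Hoxa2 and Hoxb2 in every case. Some genes that this rule names are not reported here, although they count in the totals and the lists.

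Alternatives set beforehand were a pseudocount of 0.1, no filter or a filter of 5 RPKM, median-ratio and quantile scaling, no variance trend, a fit of only the groups compared, blocks by replicate number and by runs of library numbers, a 2-fold minimum, and leaving out each library in turn. Alternatives chosen after seeing the data were limma's voom on the recovered reads, removal of each library's trend with gene length, and leaving out 3 libraries that stand apart from their regions (forebrain 1, dorsal midbrain 3 and alar plate 3). Leaving out libraries because they differ from their group lowers the spread by construction, so those counts are an upper description and not a better estimate. The tests of explanations in the closing part were all written after the results were seen. For the exchange of alar plate 3 with dorsal midbrain 3, a test by correlation with the length trend removed decided nothing and a test on genes was added after it. By the genes alone the exchange would have been argued against. Correlations in the values as deposited were then weighed too, and it was left open. First versions of 2 other tests used lists or genes chosen by hand and were replaced by tests over all fixed lists. The first versions had found 6 of 31 chosen list members raised in alar plate 3 and 4 of 27 raised in both forebrain 1 and dorsal midbrain 3. The count of genes raised in both of these libraries at first included the sex-linked genes, which follow the replicate number, and asked only for more genes than in any control pair. They were then left out and a binomial test was added. By the first rule without these genes, 1 against 0 would have argued against a mixture.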

Results

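Gene expression was measured in 5 regions of the embryonic mouse brain, at a stage when dopaminergic neurons are being born in the ventral midbrain. The ventral midbrain, dorsal midbrain, alar plate, forebrain and hindbrain were each represented by 3 libraries of 8048160 to 12170238 recovered reads. The 3 ventral midbrain libraries were close to each other, with Pearson r between 0.991 and 0.993 across genes on the log2(RPKM + 1) scale. In the other 4 regions 1 library lay apart from its pair, least so in the hindbrain. Dorsal midbrain 1 and 2 had an r of 0.995, while dorsal midbrain 3 had 0.967 and 0.971 with them. Forebrain 2 and 3 had an r of 0.990, against 0.964 and 0.960 for forebrain 1. Alar plate 1 and 2 had an r of 0.987, against 0.927 and 0.925 for alar plate 3. Hindbrain 2 and 3 had an r of 0.993, against 0.984 and 0.985 for hindbrain 1. The 3 libraries called apart below leave hindbrain 1 out. Set against read-counting error alone, which leaves out any difference between tissue samples, the chi-square per gene was at least 3.25 for every 2 libraries of a region. The RPKM values of alar plate 3 summed to 489420, against 374280 to 390992 in the other libraries, and with genes split into 4 groups by length, the median RPKM of its shortest genes was 2.57 times that of its longest, against 0.977 to 1.12 in the others.

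**Figure D1:**
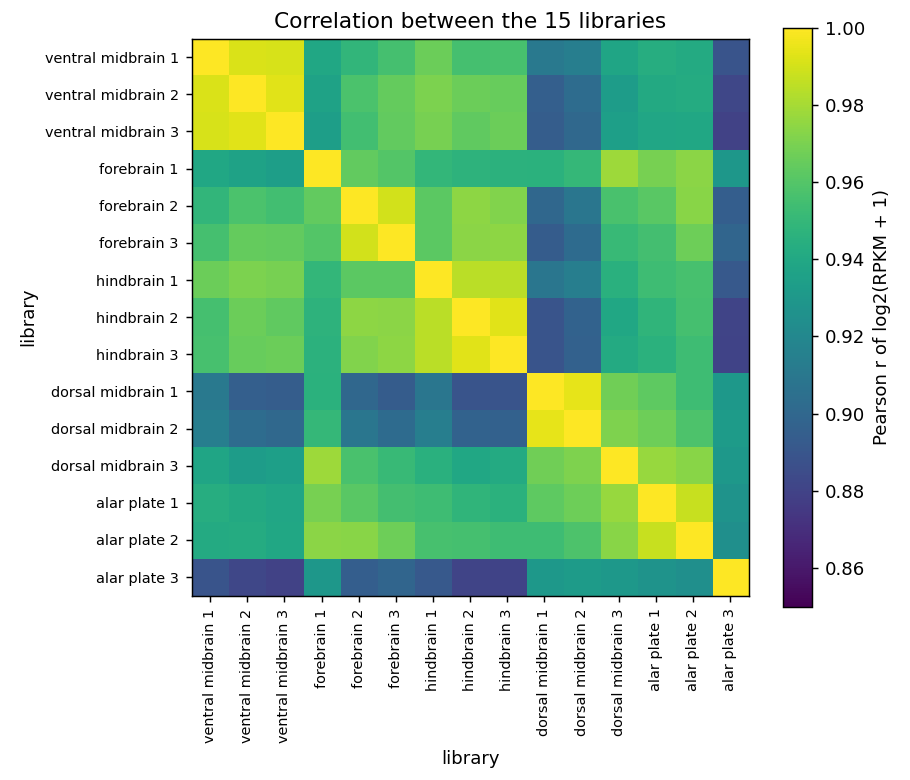
Pearson correlation of log2(RPKM + 1) across the tested genes for each pair of the 15 libraries, in a colour scale from 0.85 to 1, with libraries ordered by region on both axes. The 3 ventral midbrain libraries form a block of 0.991 or more, while forebrain 1, dorsal midbrain 3 and alar plate 3 differ from the other libraries of their regions.

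The first comparison asked which genes set the ventral midbrain, the birthplace of midbrain dopaminergic neurons, apart from the other regions. Genes of dopamine synthesis and of the dopaminergic lineage were the most strongly raised. Th, which encodes tyrosine hydroxylase, reached 76.0 ± 6.5 RPKM (SD, n = 3) against 4.29 ± 2.1 in forebrain, 2.27 ± 0.66 in alar plate, 1.78 ± 0.47 in hindbrain and 0.656 ± 0.12 in dorsal midbrain, a log2 difference of 4.71 ± 0.19 (SE) from the mean of the other regions (limma adjusted p = 1.07e-08). Ddc, the enzyme that follows Th in dopamine synthesis, was higher by 4.81, and Pitx3, a transcription factor of these neurons, by 4.29. Lmx1a and Foxa2, transcription factors of the floor plate from which these neurons arise, were higher by 5.20 ± 0.67 (adjusted p = 0.000187) and 4.71 ± 0.61 (adjusted p = 0.000207). Lmx1a was also present in forebrain 3, at 41 RPKM, and in forebrain 2, at 6.9 RPKM, against 0.21 RPKM in forebrain 1. En1, Foxa1, Kcnk9, Dmrta2 and C130021I20Rik completed the 10 largest increases among genes whose 3 ventral midbrain libraries all lay above the other 12, with log2 differences of 4.36, 4.25, 4.11, 4.05 and 4.02. Like Lmx1a, the rest of these 10 genes had fewer recovered reads in forebrain 1 than in forebrain 2 and 3. Foxa2 had 3, 340 and 557, Ddc 46, 425 and 648, and En1 1, 66 and 71 in forebrain 1, 2 and 3. Slc18a2 of the dopaminergic neuron list went the other way, with 620, 160 and 274. Nr4a2, needed for the dopaminergic transmitter identity, was higher by 3.41 (adjusted p = 0.014). It had 2882, 4027 and 3305 recovered reads in ventral midbrain 1, 2 and 3. In the same order, it had 276, 1561 and 2537 in the forebrain and 217, 1015 and 1491 in the hindbrain. The dorsal midbrain had 33, 33 and 1297, and the alar plate 81, 42 and 49. Nr4a2 was not among the genes called higher in the ventral midbrain than in each other region. Otx2 differed by 0.47, short of the threshold (adjusted p = 0.287), and Pax7, a dorsal midbrain factor, was lower at -3.09.

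By list, 16 of 20 tested members of the dopaminergic neuron list were higher and 1 was lower, with a median log2 difference of 2.79 (camera adjusted p = 0.025 with an estimated correlation), and the count was 16 and 1 when adjusted over the list alone. The fry test, which asks whether the members move one way, gave an adjusted p of 5.51e-07 for this list. Of the list results given here with an estimated correlation, all but the PBX and MEIS list (adjusted p = 0.277) were called by camera at its preset correlation. Of the 20 members of the dopaminergic progenitor and floor plate list, 17 were higher, with a median of 3.20 (adjusted p = 0.0469 with an estimated correlation), or 18 when adjusted over the list alone. The list of motor and red nucleus neurons, other cell types of the ventral midbrain, had 9 of 13 members higher, among them Nkx6-1 by 2.78 and Isl1 by 2.69 (adjusted p = 0.0178 with an estimated correlation; 9 adjusted over the list alone). The midbrain and isthmus list had 8 of 14 higher, led by En1 and En2 (adjusted p = 0.0913 with an estimated correlation; 11 adjusted over the list alone), and the hindbrain neuron list had 8 higher and 2 lower of 15, with Lhx4 higher by 3.25 and Mab21l2 lower at -3.75 (adjusted p = 0.131 with an estimated correlation; 9 and 4 adjusted over the list alone). The choroid plexus list had 3 of 4 tested members higher, Sulf1, Folr1 and Enpp2, of which Sulf1 is also in the floor plate list (adjusted p = 0.153 with an estimated correlation; 3 adjusted over the list alone).

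Genes of dorsal and GABAergic identity were lower in the ventral midbrain. Of 19 members of the tectum and dorsal neural tube list, 9 were lower and 1 higher, or 15 and 1 adjusted over the list alone, with a median of -1.82 (adjusted p = 0.0178 with an estimated correlation). Among genes whose 3 libraries all lay below the other 12, the LIM homeobox gene Lhx2 had the lowest difference, at -4.81, followed by Shox2 at -4.59, Dbx1 at -4.36, Tfap2b at -4.27, Lhx9 at -4.21, Mab21l2 at -3.75, Crabp1 at -3.70, Barhl2 at -3.69, Fgf15 at -3.27 and Pax3 at -3.12. Of 12 genes of GABAergic neurons 8 were lower, and all 12 when adjusted over the list alone, with Gad1, a GABA-synthesising enzyme, at -2.17 (adjusted p = 0.206 with an estimated correlation). The PBX and MEIS list split, with 3 members higher and 6 lower of 15 (the same numbers adjusted over the list alone), with Meis2 at -2.77 (adjusted p = 0.647 with an estimated correlation).

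In all, 1456 of 13745 genes differed between the ventral midbrain and the other regions, 1021 higher and 435 lower. The count was 2690 (1498 and 1192) without alar plate 3, 4587 (2189 and 2398) without the 3 libraries that stand apart, 1670 (1009 and 661) after quantile normalization and 791, 837 and 736 without ventral midbrain 1, 2 and 3. It fell to 520 in a fit that treats the other 12 libraries as 1 group.

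**Figure D2:**
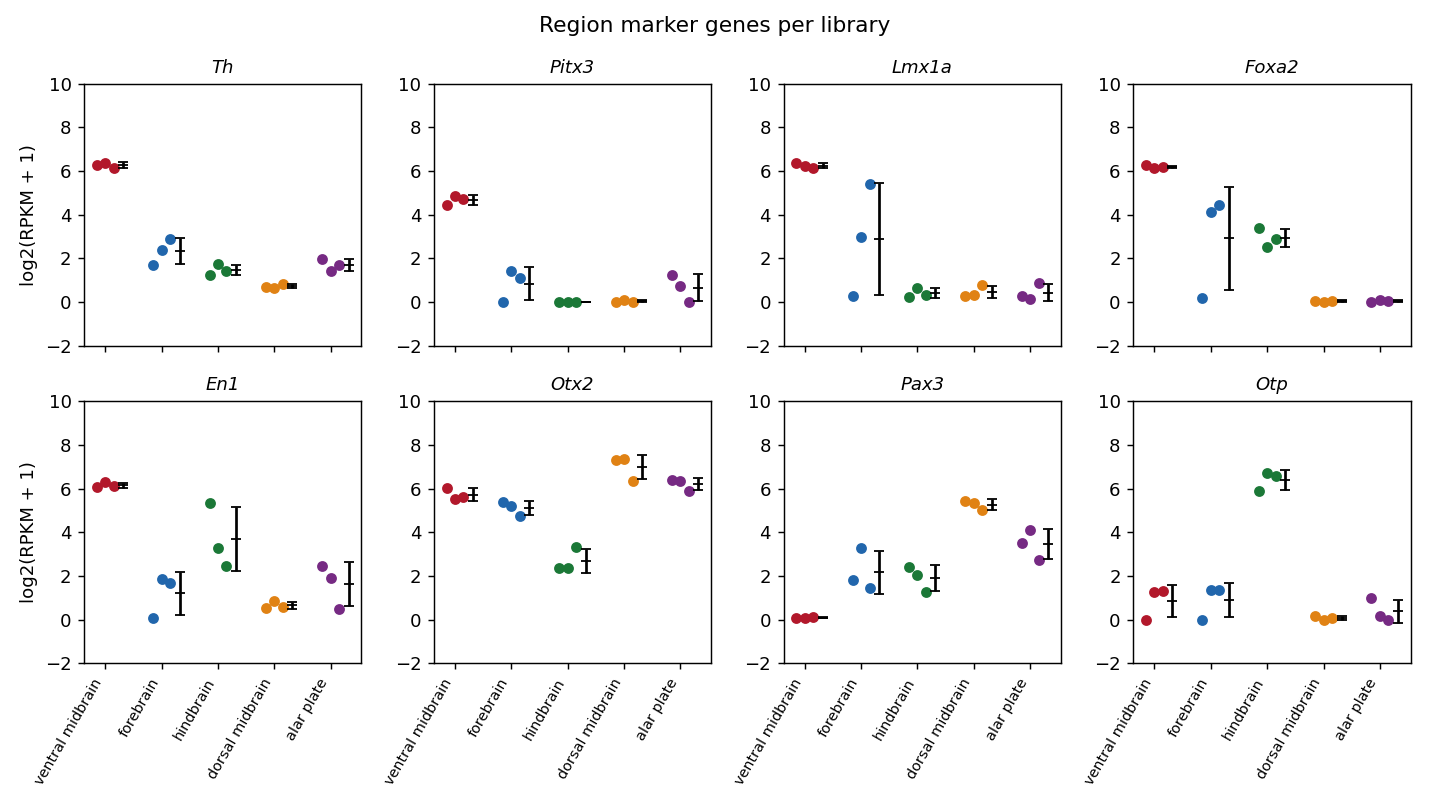
Expression of 8 region marker genes per library, with log2(RPKM + 1) on the vertical axis and the 5 regions on the horizontal axis, 1 point per library and the mean with SD as the black bar (n = 3). Th, Pitx3, Lmx1a, Foxa2 and En1 are highest in the ventral midbrain, Pax3 in the dorsal midbrain and Otp in the hindbrain, and Lmx1a varies widely between the forebrain libraries.

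The second comparison asked which genes were higher in the ventral midbrain than in every other region. It held 189 genes. The highest value was 0 in 20 simulated data sets that shared the same ventral midbrain libraries and had no region effects, so almost no calls could overlap in them, and 0.219 for independent lists. Neither gives the overlap of lists that hold differences and share libraries. With 3 ventral midbrain libraries they could not be split, so part of the overlap may come from the shared libraries. By the smallest of the 4 differences, Th led with 3.94, followed by Pitx3 with 3.83, Ddc with 3.39, the potassium channel gene Kcnk9 with 3.36, Lmx1a with 3.36, Foxa2 with 3.27, the nicotinic receptor subunit gene Chrna6 with 3.14, Foxa1 with 2.66, the neuropeptide gene Vip with 2.66 and Hepacam2 with 2.55. Without ventral midbrain 1 or 3 the count was 106 or 122, without hindbrain 3 it was 125, and without alar plate 3 it was 307. It was 455 without the 3 libraries that stand apart and 110 for genes with at least 5 RPKM.

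Against single regions, the ventral midbrain differed from the dorsal midbrain in 3280 genes, 1572 higher and 1708 lower, a split of 1816 and 1267 after median-ratio scaling. Sulf1, Spon1, Foxa2, Ddc and Foxa1 were the most raised, with log2 differences of 7.66, 7.02, 6.16, 5.96 and 5.93, and Tfap2b, Lhx2, Dbx1, Zic1 and Pax3 the most lowered, from -6.04 to -5.19. The count was 7961 without the 3 libraries that stand apart, 1498 and 1563 without dorsal midbrain 1 and 2, 1710 and 1725 without ventral midbrain 2 and 3, and 5330 with only these 2 groups fitted. Against the alar plate 1958 genes differed, 1253 higher and 705 lower, or 1124 and 959 after quantile normalization. C130021I20Rik, Ddc, Foxa2, Lmx1a and Foxa1 led upward with 6.24, 6.21, 6.14, 5.83 and 5.68, and Lhx2, Tfap2b, Lhx9, Dbx1 and Barhl2 downward, from -6.43 to -5.08. Without the 3 libraries the count was 4203 (2075 and 2128), without ventral midbrain 1, 2 and 3 it was 1148, 1114 and 1002, and with only these 2 groups it was 1007.

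Against the forebrain 1145 genes differed, 878 higher and 267 lower, or 816 and 422 after quantile normalization. En2, En1, Sulf1, Corin and Ferd3l were higher by 5.38, 4.96, 4.57, 4.46 and 4.35, and Tcf7l2, Lhx2, Shox2, Lhx9 and Bhlhe23 were lower, from -6.00 to -4.26. Without the 3 libraries the count was 4386 (2362 and 2024), with only these 2 groups fitted 1976 (1283 and 693), and at a 5 RPKM filter 717. Without ventral midbrain 1, 2 and 3 it was 689, 759 and 698. Against the hindbrain 522 genes differed, 329 higher and 193 lower. Lmx1a, Dmrta2, Th and Pitx3 were higher by 5.85, 4.93, 4.80 and 4.67, followed by Emx2, and Otp, Cyp26b1, Shox2, Mab21l2 and Meis2 were lower, from -5.54 to -3.58. Without the 3 libraries it was 2734 (1351 and 1383), and with only these 2 groups fitted 2191 (1098 and 1093). Without ventral midbrain 1, 2 and 3 it was 259, 332 and 320, and without hindbrain 2 and 3 it was 298 and 296.

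In the dorsal midbrain, genes of dorsal identity were raised, as were genes of cell division, mainly in dorsal midbrain 1 and 2. The Wnt receptor gene Fzd10 reached 91.0 ± 34 RPKM (SD, n = 3), a log2 difference of 3.84 ± 0.42 from the mean of the other regions (limma adjusted p = 0.00013). Among genes whose 3 libraries all lay above the other 12, Pax3, Tal2, Slc45a3, Nr2e1, Gas1, Rspo1, Gli3 and Gsx1 followed, with differences from 3.37 down to 2.63. Of 19 tested members of the tectum and dorsal neural tube list 16 were higher, with Zic4 at 3.54 (adjusted p = 0.0178 with an estimated correlation; 17 adjusted over the list alone). Pax7, a marker of dorsal midbrain, was higher by 2.85 (adjusted p = 0.00309), and Otx2 by 2.06. All 16 proliferation genes were higher, Top2a by 1.73 and Mki67 by 1.65, and 16 also when adjusted over the list alone, but with an estimated correlation the list's adjusted p was 0.591. Top2a stood at 145, 125 and 62.8 RPKM in dorsal midbrain 1, 2 and 3, against 63.6 in forebrain 1 and 62.7 in alar plate 3. Mki67 stood at 75.8, 63.2 and 33.6 RPKM, against 32.5 and 17.2. Dorsal midbrain 3 was close to forebrain 1 for both genes. Some other members stood as high in alar plate 3 as in dorsal midbrain 1 and 2. In recovered reads, Birc5 had 667 against 642 and 614, and Cdk1 had 1060 against 1024 and 987. Others did not, such as Cenpf with 956 against 3456 and 3299. Across genes, the deviation of alar plate 3 from the other libraries fell with gene length (Spearman -0.609). The values of single members in alar plate 3 were not corrected for that trend. Whether these members differ there for their length or for cell division was not tested. Genes of meninges and mesenchyme were also higher, 8 of 10, with 9 adjusted over the list alone and Col1a1 at 3.19 (adjusted p = 0.636 with an estimated correlation). Col1a1 stood at 21.7, 22.5 and 11.1 RPKM in the dorsal midbrain libraries, and at 38.3, 0.854 and 6.21 RPKM in those of the alar plate. Of 26 Wnt signalling genes 10 were higher and 3 lower (10 and 4 adjusted over the list alone), and of 13 endothelial genes 6 were higher (6 adjusted over the list alone). The estimated-correlation adjusted p was 0.283 and 0.675 for these lists.

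Floor plate genes were lowered in the dorsal midbrain, Sulf1 at -5.01, Spon1 at -4.74, the guidance cue Ntn1 at -3.87 and Shh at -3.29, and then, among genes whose 3 libraries all lay below the other 12, Nkx2-2, Scg2, C1ql1, Pdlim3, Slc17a8 and Fxyd7, from -3.00 to -2.36. Of the 20 dopaminergic progenitor and floor plate genes 12 were lower and 3 higher (13 and 3 adjusted over the list alone), with an adjusted p of 0.502 with an estimated correlation. Of the 20 dopaminergic neuron genes 12 were lower and 1 higher (15 and 1 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). The total was 4398 genes, 2495 higher and 1903 lower, a split that turned to 1910 and 2279 after median-ratio scaling. It was 1170 and 1523 without dorsal midbrain 1 and 2, 7320 without alar plate 3, 8834 without the 3 libraries that stand apart and 2555 with the other 12 libraries as 1 group.

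In the hindbrain, Otp, a homeobox gene of specific neuron groups, reached 85.6 ± 24 RPKM (SD, n = 3) against means of at most 1.04 in the other regions, a log2 difference of 5.84 ± 0.33 (limma adjusted p = 3.4e-07). Cyp26b1, which breaks down retinoic acid, was higher by 3.88, Tph2, the serotonin-synthesising enzyme, by 3.29, and 6330527O06Rik, Slc17a8, Skor1, Lgi3, Foxd3 and Gm5607 by 3.20 down to 2.58. All of these had their 3 hindbrain libraries above the other 12. Of 15 tested hindbrain neuron genes 7 were higher and 1 lower (9 and 1 adjusted over the list alone), with the serotonergic genes Slc6a4 at 3.76 and Fev at 2.66 (adjusted p = 0.0699 with an estimated correlation). Both were also present in the ventral midbrain, so they do not set the hindbrain apart from it. Fev had 244, 165 and 202 recovered reads in hindbrain 1, 2 and 3, and 132, 292 and 204 in ventral midbrain 1, 2 and 3. Slc6a4 had 1118, 834 and 1119, and 364, 854 and 618. The tectum and dorsal neural tube list had 5 of 19 lower (14 adjusted over the list alone; adjusted p = 0.025 with an estimated correlation). Emx2 at -3.78, Otx2 at -3.32, Fzd10 at -3.19, Tal2 at -3.15, Ccnd2 at -3.02, Lef1 at -2.78, Igfbpl1 at -2.44, Helt at -2.35, Msx1 at -1.95 and Ntng2 at -1.92 were the lowest among genes whose 3 libraries all lay below the other 12. Of 26 Wnt signalling genes 8 were lower and 2 higher (15 and 3 adjusted over the list alone; adjusted p = 0.084 with an estimated correlation). None of the 22 Hox genes passed the filter. Hoxa2 was at 0.107, 11.1 and 6.24 RPKM in hindbrain 1, 2 and 3, Hoxb2 at 0, 8.99 and 3.05, and En1 at 39.7, 8.56 and 4.55. In total 866 genes differed, 554 higher and 312 lower. The count was 505, 373 and 340 without hindbrain 1, 2 and 3, 1603 without dorsal midbrain 3, 2011 (1060 and 951) without alar plate 3 and 5174 (2506 and 2668) without the 3 libraries that stand apart. It was 467 at a 5 RPKM filter and 108 with the other 12 libraries as 1 group.

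In the forebrain, Nkx2-2, a homeobox gene of ventral progenitors, was at 18.8 ± 3.0 RPKM (SD, n = 3), a log2 difference of 2.22 ± 0.16 (limma adjusted p = 1.42e-05). Among genes whose 3 libraries all lay above the other 12, the other 9 highest, Slc24a3, Kcna6, both Pde4b rows, Gm9767, Gpm6a, Tmem150c, Ptprn and Tmem200a, were higher by 0.88 down to 0.59. The diencephalic gene Tcf7l2 was higher by 3.87 (adjusted p = 0.0123). It was at 403, 259 and 132 RPKM in forebrain 1, 2 and 3, and also at 378 in dorsal midbrain 3 and 215 in alar plate 3. Of 14 tested telencephalon genes 1, Six3, was higher at 2.39 (5 adjusted over the list alone; adjusted p = 0.0478 with an estimated correlation). Cyp26b1, Nbl1, Sox21, Igfbp2, Jag1, Gpx8, Csrp1, S100a16, Pdpn and Pls3 were lower, from -2.37 to -0.87. They were the lowest of genes whose 3 libraries all lay below the other 12. The hindbrain neuron list had 5 of 15 lower (7 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). The total was 401 genes, 85 higher and 316 lower, or 122 and 256 after quantile normalization. It was 939 (378 and 561), 75 and 127 without forebrain 1, 2 and 3, 256, 246 and 1146 (456 and 690) without dorsal midbrain 1, 2 and 3, 234, 246 and 235 without ventral midbrain 1, 2 and 3, 259 without hindbrain 3, 1133 (357 and 776) without alar plate 3 and 5972 (2580 and 3392) without the 3 libraries that stand apart. limma called 0 genes with the other 12 libraries as 1 group, while in the fit of 5 regions 2806 had an unadjusted p under 0.05, and voom on recovered reads called 197.

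In the alar plate, among genes whose 3 libraries all lay on one side of the other 12, Arl4d was higher by 1.70 ± 0.22 (limma adjusted p = 0.0013), at 9.81 ± 1.4 RPKM (SD, n = 3), followed by the neuropeptide gene Tac1 at 1.48, Car14 at 1.41, Pou3f1 at 1.36, 2610017I09Rik, Snhg8, Pou3f3, Tagln3 and Ldhb, the last at 0.47. The lowest of these were Ferd3l at -2.60, Slit2 at -2.34, Igfbp5 at -2.17, Slit1 at -2.16, Zfp536, Odz4, Odz3, Vat1l, Fndc3b and Stxbp6, the last at -1.18. Odz4 had 1031, 967 and 141 recovered reads in alar plate 1, 2 and 3, so part of its difference came from alar plate 3. In that library long genes had lower values than short ones, as given above. That trend was not removed from the differences given here in either direction. Of 20 floor plate genes 13 were lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation), and of 20 dopaminergic neuron genes 8 were lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.223). The tectum and dorsal neural tube list had 6 higher and 1 lower of 19 (7 and 2 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation), with Tfap2b at 3.29 and Barhl2 at 2.66. The total was 640 genes, 171 higher and 469 lower. It was 1754 without alar plate 1, 1124 without forebrain 1, 425 and 409 without ventral midbrain 2 and 3, 1683 (695 and 988) without the 3 libraries that stand apart and 3 with the other 12 libraries as 1 group.

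**Figure D3:**
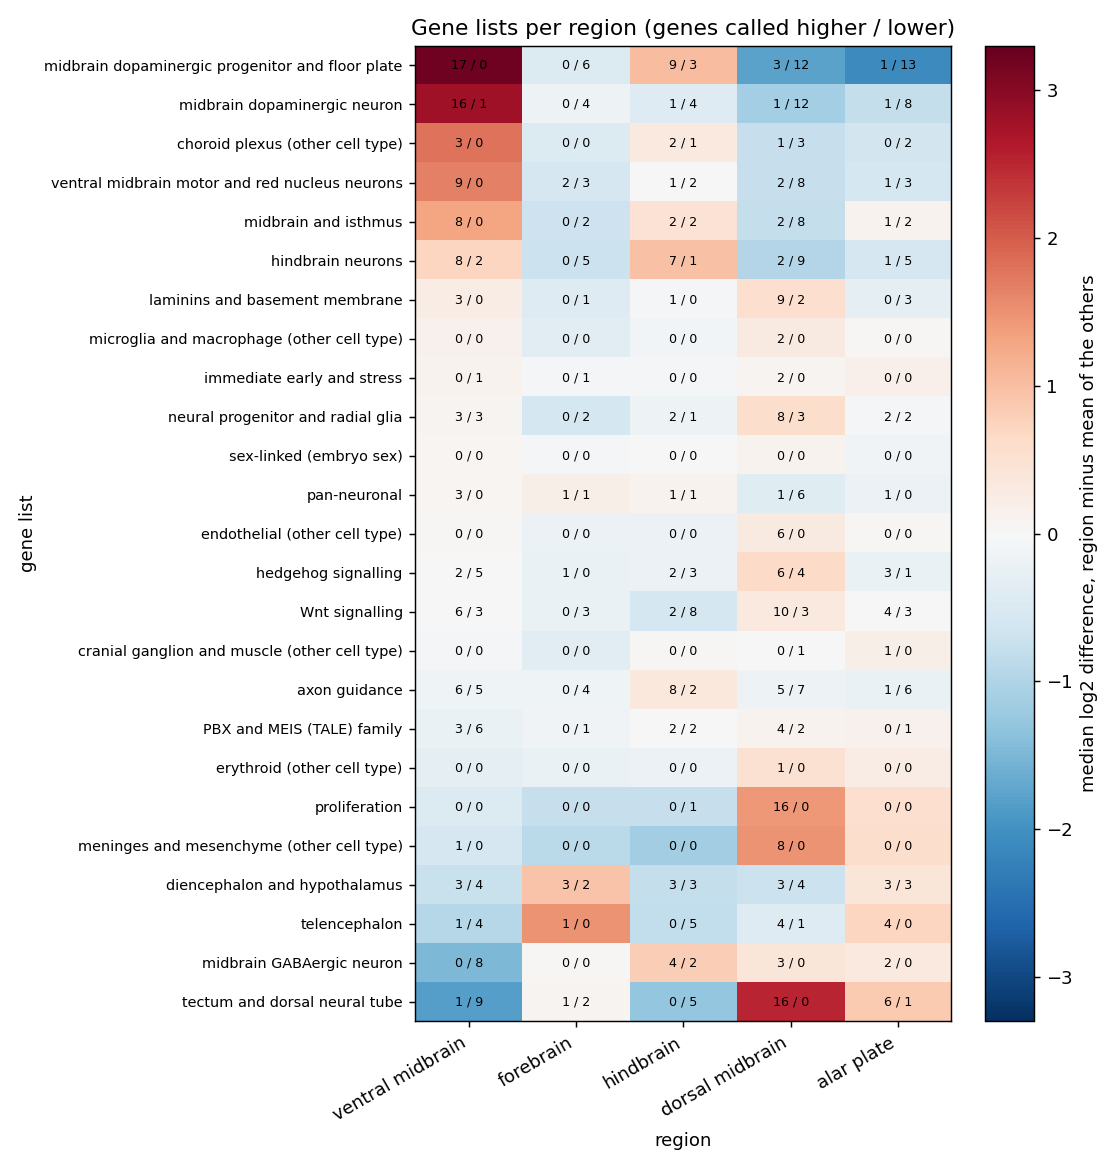
Median log2 difference of each fixed gene list (vertical axis) in each region minus the mean of the other regions (horizontal axis), as colour from -3.3 to 3.3, with the numbers of members called higher and lower written in each cell. The 2 dopaminergic lists have medians of 3.20 and 2.79 in the ventral midbrain, and the tectum and dorsal neural tube list has 16 members higher in the dorsal midbrain.

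**Figure D4:**
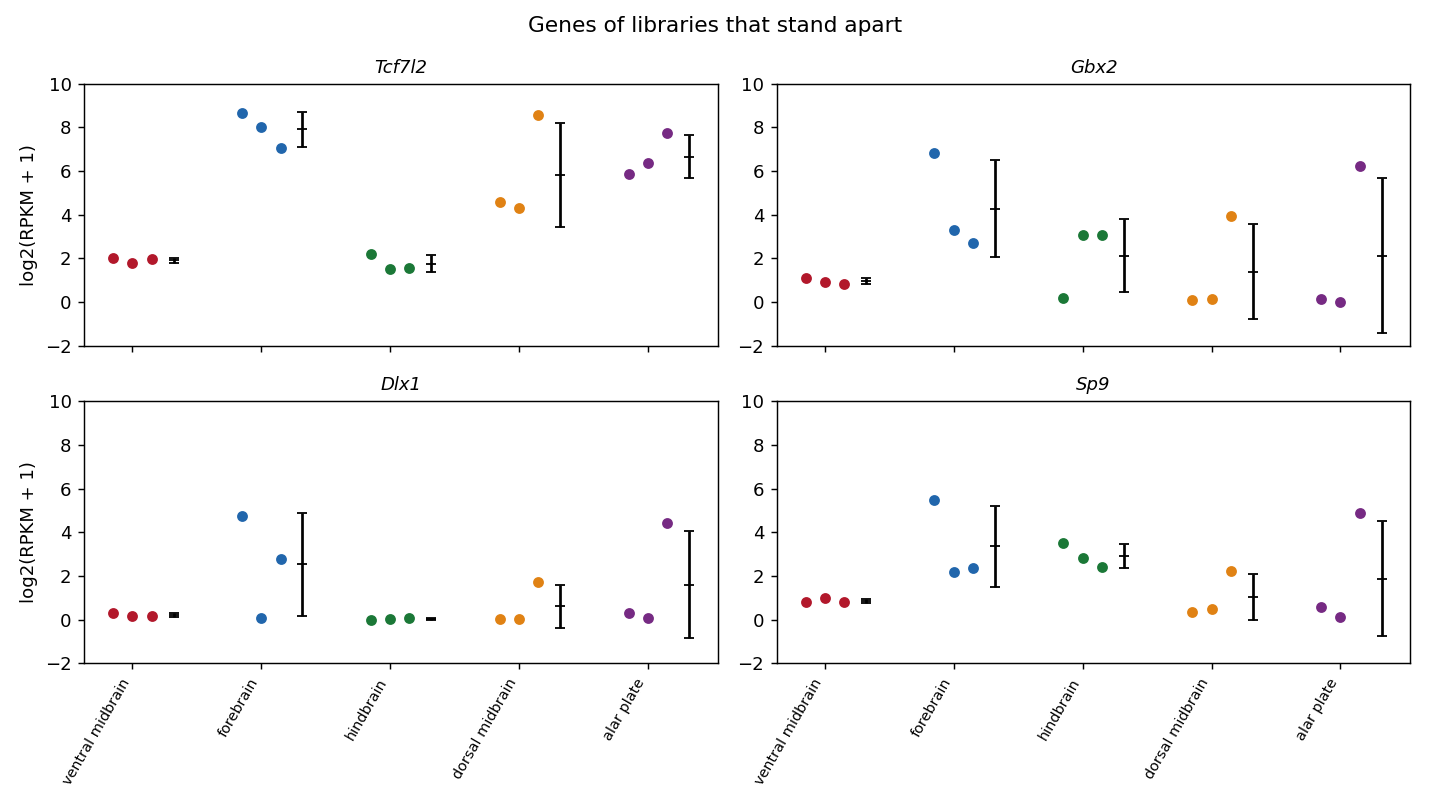
Expression of 4 genes per library, with log2(RPKM + 1) on the vertical axis and the 5 regions on the horizontal axis, 1 point per library and the mean with SD as the black bar (n = 3). Tcf7l2 stands high in dorsal midbrain 3 (378 RPKM), and Gbx2 in forebrain 1 (111 RPKM) and alar plate 3 (73.0 RPKM), where Dlx1 (20.2 RPKM) and Sp9 (28.6 RPKM) are also above the other alar plate libraries.

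The dorsal midbrain and the alar plate differed in 230 genes, 173 higher and 57 lower in the dorsal midbrain, or 105 and 66 after quantile normalization. With the replicate block more genes were called, as given in the part on processing. Wnt1, a signal of the dorsal midline and isthmus, was at 7.14 ± 2.1 RPKM (SD, n = 3) against 0.158 ± 0.16, a log2 difference of 2.79 ± 0.18 (limma adjusted p = 1.37e-05), and Fzd10, Odz3, Wnt2b and Flnc were higher by 2.45, 2.25, 2.08 and 1.94. Six3, Six3os1, Nkx2-2, Pdlim3 and C1ql4 were lower, at -3.11, -2.95, -2.73, -2.72 and -2.10. Six3os1 is transcribed opposite to Six3, and without strand the reads of such a pair cannot be told apart. Of 19 tectum and dorsal neural tube genes 3 were higher, Gdf7, Bmp6 and Dmbx1 (10 adjusted over the list alone; adjusted p = 0.084 with an estimated correlation). The count was 48, 46 and 1230 without dorsal midbrain 1, 2 and 3, 783, 75 and 486 without alar plate 1, 2 and 3, 5370 (2957 and 2413) without the 3 libraries that stand apart and 15 with only these 2 groups fitted.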

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

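Voom, the removal of the length trend and leaving out 3 libraries together were chosen after seeing the data. Causes were not tested unless the setting itself shows them. None of up to 417 results of named genes changed direction under any setting. Most were named for large differences, many without overlap between libraries, so few reversals could arise, and a few, such as Otx2, were not called. Calls were lost for 261 in fits of only the groups compared and for 74 under voom. Without dorsal midbrain 2 and 1 it was 74 and 71, and elsewhere at most 61. Depth limits genes near the floor of 3 reads.

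Leaving out forebrain 1, dorsal midbrain 3 and alar plate 3, which lowers the spread by construction, gave 4587 genes for the ventral midbrain, 5972 for the forebrain, 5174 for the hindbrain, 8834 for the dorsal midbrain and 1683 for the alar plate, 7961, 4203, 4386 and 2734 for the ventral midbrain against dorsal midbrain, alar plate, forebrain and hindbrain, 5370 for dorsal midbrain against alar plate and 455 for genes higher in ventral midbrain than in each region. With a 5 RPKM filter, which tests fewer genes, counts were 212 for the forebrain, 467 for the hindbrain, 396 for the alar plate, 717 and 312 for the ventral midbrain against forebrain and hindbrain, and 110 for the shared set. A 2-fold minimum left 475, 79, 324, 727 and 163 genes for ventral midbrain, forebrain, hindbrain, dorsal midbrain and alar plate, 1169, 709, 482 and 297 for the ventral midbrain against dorsal midbrain, alar plate, forebrain and hindbrain, 84 for dorsal midbrain against alar plate and 94 for the shared set. With only the groups compared, counts were 520, 0, 108, 2555 and 3 in the same order of regions, 5330, 1007, 1976 and 2191 for the pairs with ventral midbrain, and 15 for dorsal midbrain against alar plate. For the forebrain, limma's voom on recovered reads (99.7% of genes whole) gave 197 and the removed length trend 655 genes.

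Leaving out 1 library at a time (for pairs of regions only their own 6, so the effect of the other 9 on these counts was not run), counts ranged from 736 to 2690 for the ventral midbrain, 75 to 1146 for the forebrain, 340 to 2011 for the hindbrain, 1170 to 7320 for the dorsal midbrain, 409 to 1754 for the alar plate, 1498 to 4003, 1002 to 2888, 689 to 962 and 259 to 474 for the ventral midbrain against dorsal midbrain, alar plate, forebrain and hindbrain, 46 to 1230 for dorsal midbrain against alar plate, and 106 to 307 for the shared set. Of 57 list results 2 reversed. Calls were lost for 13 without the 3 libraries, 9 without alar plate 3, 7 under voom, 7 of 56 at the 5 RPKM filter, 6 with the length trend removed and at most 6 elsewhere. The median of midbrain dopaminergic progenitor and floor plate, forebrain against the mean of the other regions, was -0.45, ranged from -0.993 without forebrain 3 to 0.045 without forebrain 1, and was 0.123 without the 3 libraries. That of axon guidance, alar plate against the mean of the other regions, was -0.22 and ranged from -0.404 without alar plate 1 to -0.00662 without alar plate 3, where the test turned, as it did without the 3 libraries (-0.0298).

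Replicate numbers are shared between regions, but not every pair of same-numbered libraries deviated together: the median correlation of deviations was 0.236 (lowest -0.175, 18 of 30 above 0.1), and 12 of 15 libraries correlated best with their own number. All 3 pairs were above 0.1 for ventral midbrain with forebrain, ventral midbrain with hindbrain and forebrain with hindbrain, and all 3 were negative for dorsal midbrain with alar plate. With the replicate block, dorsal midbrain against alar plate gave 822 genes (548 and 274), and the other 10 counts stayed within 1.5 times.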

Other observations

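All tests of explanations below were chosen only after the results they bear on were seen, while the gene lists were fixed beforehand. In the ventral midbrain, 6 of 26 Wnt signalling genes were higher and 3 lower (7 and 4 adjusted over the list alone), with Wnt5a at 2.93, a median near 0 and a mean of 0.18. Of 13 hedgehog genes 2 were higher and 5 lower (2 and 6 adjusted over the list alone), with Shh at 3.72, Gli3 at -2.38, a median near 0 and a mean of -0.29. Axon guidance genes split into 6 higher and 5 lower of 28 (8 and 6 adjusted over the list alone), with Ntn1 at 3.25 and Slit2 at 3.16, a median of -0.15 and a mean of 0.26. Laminins and basement membrane genes had 3 of 16 higher (5 adjusted over the list alone), Lama5 at 1.14, but an adjusted p of 0.717 with an estimated correlation. Neurofilament genes Nefl and Nefm were higher by 1.97 and 1.82 among 16 pan-neuronal genes, of which 3 were called (3 adjusted over the list alone). Neural progenitor and radial glia genes had 3 higher and 3 lower of 17 (5 and 4 adjusted over the list alone), the diencephalon and hypothalamus list 3 higher and 4 lower of 13 (3 and 5), and the immediate early and stress list 1 lower of 8 (1), Dusp1. The telencephalon list had 1 higher and 4 lower of 14 (1 and 4), with an adjusted p of 0.153 with an estimated correlation. limma called 0 members of the erythroid (7 tested), endothelial (13), microglia and macrophage (9) or cranial ganglion and muscle (4) lists there, and 0 when adjusted over each list alone, with 0, 1, 3 and 0 members at an unadjusted p under 0.05. It also called 0 of 16 proliferation genes (0 adjusted over the list alone, 1 at an unadjusted p under 0.05). Of 10 meninges and mesenchyme genes 1, Postn, was higher (1 higher and 4 lower adjusted over the list alone), with 6 at an unadjusted p under 0.05 and an adjusted p of 0.717 with an estimated correlation.

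Sex-linked genes followed the replicate number and not the region. Xist was between 55.1 and 88.4 RPKM in the 10 libraries numbered 1 and 2 and between 0.096 and 0.217 in the 5 libraries numbered 3, while the Y-linked gene Ddx3y was at most 0.0344 RPKM in the former and between 6.41 and 9.72 in the latter. limma called 0 of the 5 sex-linked genes in the 10 comparisons between regions, with 0 at an unadjusted p under 0.05. In each region, library 3 thus came from other embryos than libraries 1 and 2, while libraries 1 and 2 may share embryos. If libraries of the same number share embryos across regions, which the labels do not state, fits without the replicate block leave that pairing out. The sex-linked genes were named after their values were seen, and no comparison was made by them.

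Chance regrouping of the libraries was checked for each count. Among 100 relabellings of the 15 libraries into 5 groups of 3, the real labels included, 1 gave as many genes as the ventral midbrain (1456, highest other 3), 1 as the forebrain (401, highest other 7), 1 as the hindbrain (866, highest other 615, which grouped the ventral midbrain libraries), 1 as the set higher in the ventral midbrain than in each other region (189, highest other 0), 2 as the alar plate (640, highest other 5400) and 3 as the dorsal midbrain (4398, highest other 5513), so chance is excluded for these only as a random grouping of all 15 libraries. Such a relabelling moves the differences between the other regions into the spread, and with the other 12 libraries as 1 group the real labels gave 0 genes for the forebrain and 3 for the alar plate, so it does not test 1 region by itself. The highest value for the alar plate and for the dorsal midbrain came from a group of dorsal midbrain 1 and 2 with alar plate 3, which points to a structure of the samples. For pairs of regions only 10 splits exist, too few for a share under 0.05. The counts with their highest other split were 3280 and 1 for the ventral against the dorsal midbrain, 1958 and 0 against the alar plate, 1145 and 0 against the forebrain, 522 and 0 against the hindbrain, with 1 split as large each, and 230 and 2132 for the dorsal midbrain against the alar plate, with 2 splits as large. The 2132 genes also came from dorsal midbrain 1 and 2 with alar plate 3.

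Alar plate 3 stood apart from alar plate 1 and 2. A trend with gene length as the whole cause is argued against, since with each library's length trend removed its mean correlation with the other 2 was 0.943, below the lowest within-region value of the other libraries, 0.958, by more than their SD of 0.0128. An exchange of its label with dorsal midbrain 3 cannot be told apart from other causes, because 2 kinds of values disagree. The first kind, 41 genes chosen to part dorsal midbrain 1 and 2 from alar plate 1 and 2 with the length trend removed, goes against it, but they are not independent of each other. Dorsal midbrain 3 lay nearer the alar plate at 24.4% of them (95% exact interval 12.4 to 40.3) and alar plate 3 nearer the dorsal midbrain at 41.5% (26.3 to 57.9). In the values as deposited these were 10 of 40 (12.7 to 41.2%) and 18 of 40 (29.3 to 61.5%). Correlations across all genes go with an exchange in the values as deposited, where both libraries lay nearer the other region. There dorsal midbrain 3 had 0.975 with the alar plate pair and 0.969 with its own, and alar plate 3 had 0.931 with the dorsal midbrain pair and 0.926 with its own (largest SD 0.00251). With the length trend removed these were 0.974 and 0.968, and 0.944 and 0.943 (largest SD 0.00268). Tissue of another place in the dissection stays open and is a candidate explanation, as 2 fixed lists of other places, telencephalon (Pax6, Dlx1, Dlx2, Dlx5 and Sp9) and floor plate (3 of 20, some of them also known from the telencephalon), had more members 4-fold above both others than all genes had (adjusted Fisher exact p = 1.97e-09 and 9.68e-05; Dlx1 at 20.2 and Sp9 at 28.6 RPKM), as did tectum (5 of 19), Wnt (3 of 26, Rspo2 shared with floor plate) and sex-linked genes (4 of 5), but not diencephalon (1 of 13, adjusted p = 0.114). These list tests held only genes with an RPKM of at least 1 in at least 3 libraries, so genes reaching it in alar plate 3 alone were left out. Fezf1 of the diencephalon list was left out, with 287 recovered reads there against 2 and 0 in alar plate 1 and 2. Rax of that list, also left out, went the other way, with 8 against 24 and 42. The diencephalon result therefore decides little. Tbr1 at 23.2 RPKM and Ttr at 89.3 RPKM, both under 1 RPKM in every other library, were left out too. They were chosen after their values were seen, and no cause of these 2 values was tested.

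Forebrain 1 and dorsal midbrain 3 correlated with each other at 0.978, more than with the other libraries of their own regions. The same held with alar plate 1 and 2, at 0.969 and 0.974 for forebrain 1 and 0.977 and 0.974 for dorsal midbrain 3. An exchange of the labels of forebrain 1 and dorsal midbrain 3 is argued against, since the larger of the differences between the other region and their own was -0.0142, with a largest SD of 0.0038. A partial mixture of both regions as the whole cause cannot be told apart from other causes, because outside the sex-linked genes 1 gene, Snord57, was 2-fold above the 4 other libraries in both, against 0 in the 8 control pairs, too few to decide (exact binomial p = 0.111). With sex-linked genes counted, forebrain 3 with dorsal midbrain 3 had 4, all Y-linked. Tissue of a common other place cannot be told apart either. The deviations of both libraries from their regions correlated at -0.358 across genes, which also follows if that place lies between the regions in expression. The list test cannot decide, since only Snord57 passed its bar and is in no list. A gene that forebrain 2 and 3 also express could hardly pass. Tcf7l2, for example, had 20289 recovered reads in dorsal midbrain 3 against 1235 and 1081 in dorsal midbrain 1 and 2. In forebrain 1 it had 18450 against 11342 and 7454 in forebrain 2 and 3. Six3 was higher in dorsal midbrain 3 too (240 against 0 and 2) but lower in forebrain 1 (283 against 707 and 711).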
